A study of Mus musculus with 6 samples.

How the data were processed

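RNA sequencing of 6 mouse libraries was analysed from the tables of genes and transcripts that the authors deposited. Per the labels, every library came from bone marrow derived macrophages of C57BL/6J mice with lipopolysaccharide treatment, 3 from mice with floxed Piezo1 alleles and 3 from mice that also carried Lyz2-Cre. Per the labels' protocols, polyadenylated RNA was purified, the second cDNA strand was made with dUTP, which keeps the strand of origin, and paired reads of 150 bases were sequenced. Libraries were grouped by their titles. The submitters' processing notes name the genome build GRCm39. The coordinates in the deposited tables were compared with the GRCm38 annotation, in which 99.7% of the gene identifiers were found and 90.7% of those had the same start and end, so coordinates are given here as the tables print them, on GRCm38. The aligner, the assembler, the counting program and their settings, including whether reads were counted by strand, are not given in the sources used here.

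The deposited gene table held estimated counts for 55401 genes and the deposited transcript table estimated counts for 142604 transcripts, both in whole numbers. They were taken as estimated (expected) counts because at least 99.94% of the non-zero transcript counts in each library lay within 1 count of the transcript's FPKM times its length over a constant for that library. The tests had been planned for counts of reads. Since the authors had already rounded the deposited estimated counts, no further rounding changed them, and the planned test was used. The authors also deposited FPKM values (fragments per kilobase of transcript, scaled to library size) for 30923 genes and 87841 transcripts, and per the file headers the transcript length in bases. All counts printed beside the FPKM values equalled those of the count tables. No table held a line without a gene or columns of other samples, and 67 gene symbols were shared by more than 1 identifier.

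Each comparison used edgeR 4.0.16 in R 4.3.3 with TMM factors, the default filterByExpr filter (a minimum count of 10 and a minimum total of 15), the quasi-likelihood F test with robust dispersion and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are those of libraries labelled Lyz2-Cre over floxed libraries, and no replicate block was used. Levels per library are CPM values, the usual scaling of a count to library size, computed here from the deposited counts with TMM library sizes. Means are given with SD over 3 libraries per group. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. A count of 0 allows up to 3 counts, which is 0.0457 to 0.0599 CPM. Intervals of fold changes are 95% t intervals around the edgeR fold change. They use an SE taken from the F statistic and the degrees of freedom left after the group means, so they need not match edgeR's p-values. The limits for a count of 0 cover counting error only. Within-group pairs of libraries differed by a chi-square of 106 to 529 per degree of freedom over the genes, so no library was a duplicate of another of its group.

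The comparison, the tests, the alternatives, 33 gene lists and the rule for named genes were chosen before the data were examined. The lists cover macrophage activation states, PI3K/AKT signalling, mechanosensing, metabolism, stress, the cell cycle and markers of other cell types. They held 558 gene names, of which 13 were absent from the gene table. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. The rule named Piezo1, Lyz2 and Spp1 in any case, and called genes by the size of their change. With fewer than 10 genes called, it named instead the 10 genes with the smallest unadjusted p in each direction that had an official symbol and a mean of at least 1 CPM in either group. It also named the 4 members with the highest mean of the M2, M1 and PI3K/AKT core lists, 1 of which is not reported here. Other genes named in the text were chosen after their values were seen.

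A list of 18 cardiomyocyte genes and a list of 16 abundant macrophage genes were written after the most abundant genes had been seen. A list of 35 genes of stomach and intestinal epithelium and a list of 30 liver genes were written after the levels of some of their genes had been seen. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) with and without a minimum mean FPKM of 0.5, limma on log2(FPKM + 0.1) with that minimum, a replicate block and leaving out each library in turn. Added after the data were seen were a term that separates the 2 libraries with stomach and intestinal transcripts from the other 4, a comparison of the library labelled Lyz2-Cre 2 with the 3 floxed libraries, a comparison of 2 libraries with 2, a fit without mitochondrial genes, a fit without robust dispersion, and the pathways of the KEGG column in place of the lists.

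The test was tried on simulated counts made from the means and library sizes of these libraries, with 50 genes changed at each fold. Of 17304 genes tested, edgeR recovered 0% of those changed 2-fold, 28% of those changed 4-fold, 56% of those changed 8-fold and 64% of those changed 16-fold, and it called 6 unchanged genes. DESeq2 recovered 8%, 64%, 80% and 86% at these folds and called 77 unchanged genes. The same test on transcripts recovered 0 of 50 at each fold, so it had no power there. A simulated 2-fold rise of the PI3K/AKT core list was called by camera with the preset correlation, at an adjusted p of 1.32e-23, and with an estimated correlation, at 0.00983, and 0 of the 31 other lists were called. The simulated genes varied independently. In the real libraries the estimated correlation reached 0.98, for the interferon-gamma inducible GTPases. The simulation therefore does not show how often camera calls unchanged lists here.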

Results

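The data are RNA sequencing counts from 6 mouse libraries, all labelled as bone marrow derived macrophages with lipopolysaccharide (LPS), a component of the bacterial outer membrane that activates macrophages. In 3 libraries the label gives floxed alleles of Piezo1, a mechanically activated cation channel. The other 3 are labelled as also carrying Lyz2-Cre, a Cre recombinase expressed from the lysozyme 2 gene in myeloid cells, and as a conditional knockout of Piezo1. The labels name a dose of 12 mg per kg for mice and do not say whether mice or cultured cells received the LPS. Libraries are named here as floxed 1 to 3 and labelled Lyz2-Cre 1 to 3. The counts summed to 58011994, 61032081 and 56844600 in the floxed libraries and to 59368922, 60448649 and 61420576 in those labelled Lyz2-Cre, with 22601 to 23910 genes above 0. Genes of the mitochondrial genome held 24.5% to 36.7% of the counts, the highest share being in floxed 3.

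Piezo1 was not lower in the libraries labelled Lyz2-Cre. Piezo1 (ENSMUSG00000014444, chromosome 8, 122481698 to 122551329 on the minus strand, GRCm38) was at 47.9, 43.5 and 38.2 CPM in the floxed libraries and at 46.2, 50.5 and 47.2 CPM in those labelled Lyz2-Cre. The means were 43.2 ± 4.85 and 47.9 ± 2.24 CPM (SD, n = 3 each), and the deposited FPKM were 2.94 to 4.48 and 4.22 to 4.64. The log2 fold change was 0.15 (95% interval -0.29 to 0.59), and the adjusted p was 0.9999 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The knockout of the label was thus not seen in these counts, so directions below are those of libraries labelled Lyz2-Cre. Macrophage genes took a small share of the counts, as described below, and Lyz2-Cre is expressed in myeloid cells. The Piezo1 level of a whole library therefore does not decide whether the label is right. The whole-gene count also holds reads from outside the floxed exons, which the labels do not name.

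Spp1, which encodes the secreted phosphoprotein osteopontin and is named in the series title, was higher in each library labelled Lyz2-Cre than in any floxed library. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050 on the plus strand, GRCm38) was at 2.47, 1.35 and 0.96 CPM in the floxed libraries and at 9.22, 5.76 and 8.98 CPM in those labelled Lyz2-Cre. The means were 1.59 ± 0.785 and 7.99 ± 1.93 CPM (SD, n = 3 each), a 5.01-fold difference. Its log2 fold change was 2.33 (SE 0.44, 95% interval 1.11 to 3.54). EdgeR gave it an unadjusted p of 0.00147 and an adjusted p of 0.9999, so it did not pass over all genes tested. DESeq2 gave a log2 fold change of 2.34 at an adjusted p of 0.0012. On counts simulated from these libraries, DESeq2 called 77 unchanged genes and edgeR 6. The library labelled Lyz2-Cre 2, which had the lowest stomach and intestinal transcripts of its label as described below, had a log2 fold change of 1.85 over the floxed libraries, a value of 1 library that does not test the label. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321 on the minus strand, GRCm38), the lysozyme gene of macrophages whose locus carries the Cre, was at 42.6, 31.6 and 345 CPM in the floxed libraries and at 3.30, 37.2 and 14.9 CPM in those labelled Lyz2-Cre. Its log2 fold change of -2.92 (SE 1.24) had an adjusted p of 0.9999 by edgeR and was -1.01 without floxed 3. Counts of the Lyz2 locus can also depend on the inserted Cre.

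**Figure D1:**
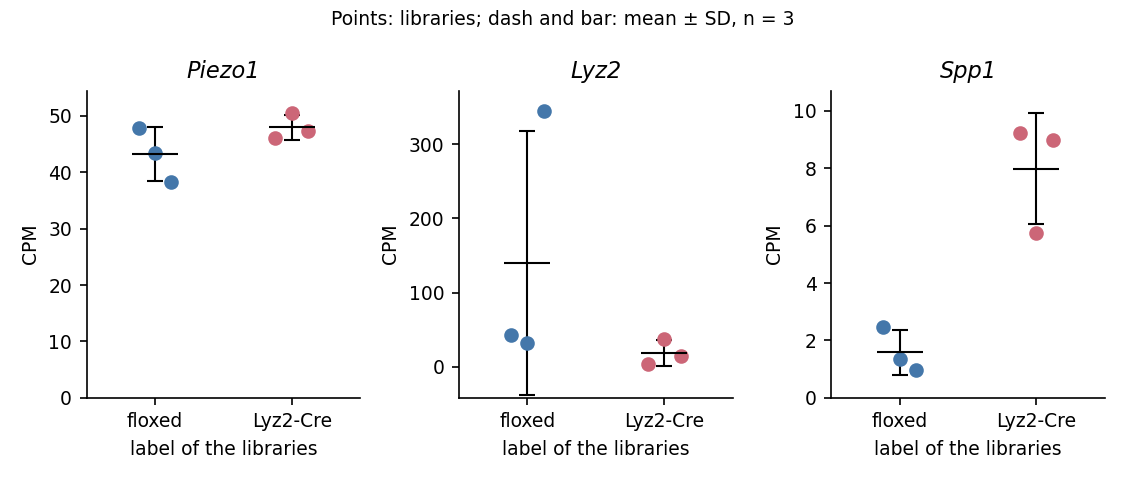
CPM of Piezo1, Lyz2 and Spp1 on linear axes in the 3 floxed libraries and the 3 libraries labelled Lyz2-Cre, with points for libraries, a dash for the mean and a bar for the SD. Piezo1 overlaps between the labels, Lyz2 is at 345 CPM in floxed 3, and Spp1 lies at 0.96 to 2.47 CPM in floxed libraries and 5.76 to 9.22 CPM in those labelled Lyz2-Cre.

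Heart muscle genes were among the most abundant transcripts in every library. The 18 cardiomyocyte genes took 4.18% to 7.90% of all counts, with Myh6, the alpha myosin heavy chain of the atria and ventricles, at 4752 to 15591 CPM and Tnnt2, cardiac troponin T, at 4375 to 5554 CPM. The 16 abundant macrophage genes took 0.0283% to 0.0680% of the counts. The median level of the endothelial markers was 63.8 to 70.0 CPM and that of the stromal and fibroblast markers 44.0 to 78.3 CPM, beside 8.59 to 21.5 CPM for the macrophage identity genes such as Csf1r, the receptor of macrophage colony stimulating factor, at 16.6 to 41.2 CPM. None of the 18 cardiomyocyte genes was called by edgeR between the labels, and Myh6 averaged 8064 ± 2940 and 10350 ± 5430 CPM (SD, n = 3 each).

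**Figure D2:**
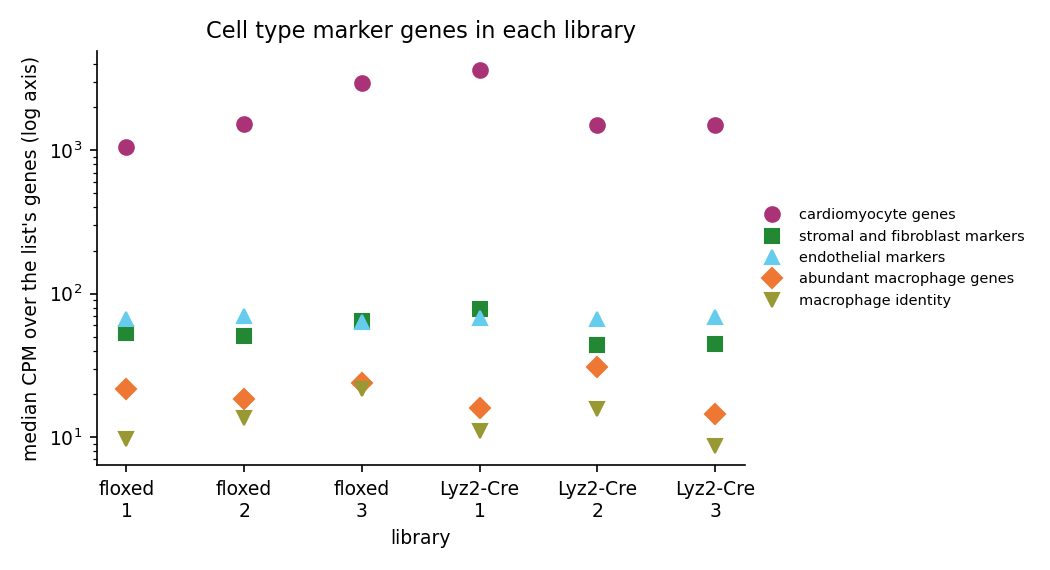
Median CPM on a log axis of 5 lists of cell type genes in each of the 6 libraries, with 1 symbol for each list. The cardiomyocyte genes have medians of 1050 to 3658 CPM, above the endothelial, stromal and macrophage genes in every library.

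Transcripts of stomach and intestinal epithelium were high in the libraries labelled Lyz2-Cre 1 and 3, and transcripts of liver in every library but Lyz2-Cre 1. The 35 stomach and intestinal genes summed to 19.9, 18.2 and 26.0 CPM in the floxed libraries and to 830, 22.1 and 811 CPM in those labelled Lyz2-Cre 1, 2 and 3. Fabp2, the intestinal fatty acid binding protein, was at 143, 1.06 and 124 CPM in these 3, and Pgc, the stomach enzyme precursor pepsinogen C, at 119, 0.80 and 159 CPM. Epcam, an adhesion protein of epithelia, had a count of 0 in each floxed library and was at 14.8, 0.26 and 11.2 CPM in those labelled Lyz2-Cre. The 30 liver genes summed to 1260, 1338 and 1637 CPM in the floxed libraries and to 99.3, 1992 and 923 CPM in those labelled Lyz2-Cre, with Alb, serum albumin, at 2.13 CPM in Lyz2-Cre 1 and 213 to 708 CPM in the other 5. EdgeR tested 18 of the stomach and intestinal genes and all 30 liver genes and called 0, while its filter, which asks for counts in 3 libraries, removed the other 17. Without Lyz2-Cre 2 it called 6 stomach and intestinal genes higher and 2 liver genes lower.

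**Figure D3:**
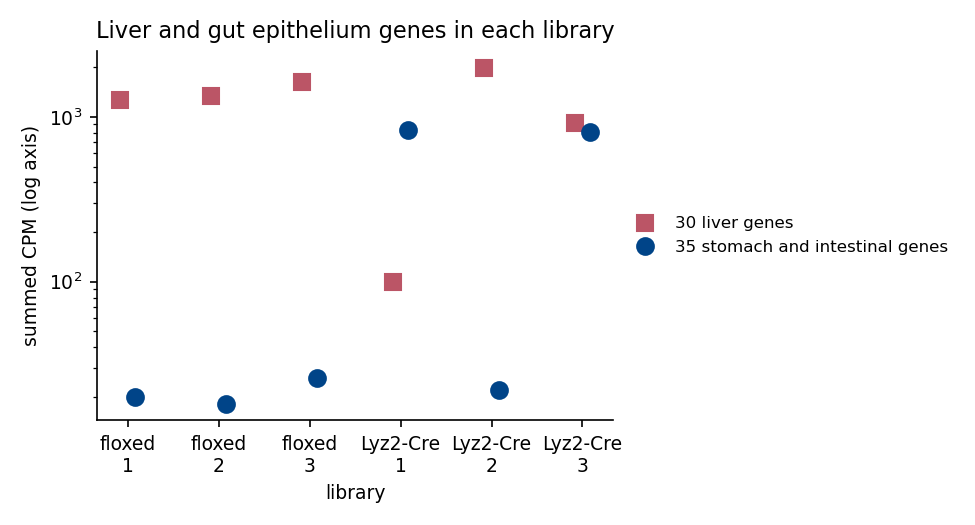
Summed CPM on a log axis of 30 liver genes (squares) and of 35 stomach and intestinal genes (circles) in each library. The stomach and intestinal genes are at 830 and 811 CPM in the libraries labelled Lyz2-Cre 1 and 3 and at 18.2 to 26.0 CPM in the other 4, and the liver genes are lowest, at 99.3 CPM, in Lyz2-Cre 1.

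Among the genes of smallest p over all genes, Apoa4, an apolipoprotein of intestinal lipid transport on the stomach and intestinal list, was at 0.76, 0.78 and 1.04 CPM in the floxed libraries and at 132, 3.89 and 127 CPM in those labelled Lyz2-Cre, a log2 fold change of 6.67 (SE 1.32). Krt8, a keratin of simple epithelia, was at 1.45 to 1.63 CPM and at 22.2, 2.80 and 21.2 CPM. Mgam, a starch-digesting enzyme of the intestinal brush border, and the cytochrome P450 Cyp3a13 had log2 fold changes of 4.29 and 2.45, and both were lowest in Lyz2-Cre 2 among the libraries labelled Lyz2-Cre, at 1.30 and 2.67 CPM. Gsdma2, a gasdermin, had 4, 0 and 0 counts in the floxed libraries and 165, 23 and 72 in those labelled Lyz2-Cre. Ifi27l2b had a log2 fold change of 2.52. Arg2, the mitochondrial arginase, averaged 0.26 ± 0.220 and 2.49 ± 0.912 CPM, Msln, mesothelin of serosal linings, 0.29 ± 0.109 and 1.84 ± 0.964 CPM, and Slc39a4, a zinc importer, 0.34 ± 0.148 and 1.54 ± 0.609 CPM (SD, n = 3 each).

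Among the lower genes, Bnip3, a mitophagy receptor induced by hypoxia, averaged 199 ± 16.4 CPM in floxed libraries and 130 ± 2.61 CPM in those labelled Lyz2-Cre (SD, n = 3 each), a log2 fold change of -0.61 (SE 0.16). Scd1, the stearoyl-CoA desaturase, averaged 66.4 ± 15.4 and 32.9 ± 12.5 CPM, and Ramp2, a partner of the adrenomedullin receptor in vessels, 37.7 ± 1.76 and 24.96 ± 4.66 CPM. Chkb, a choline kinase, Mien1 and Slirp, an RNA-binding protein of mitochondria, had log2 fold changes of -0.47, -0.56 and -0.54, and Dusp23 and Cfap300 had -1.11 and -1.51. Ugt1a6a, at -1.75, shares exons with its gene cluster, and Rn7s2, at -1.07, has near-identical copies, so their counts are uncertain.

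None of these differences passed the test over all genes. Of 17920 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, the smallest adjusted p being 0.9999. At an unadjusted p under 0.05 there were 242 genes, 186 higher and 56 lower, where chance gives 896. The groups did not overlap in 878 genes, 4.90% of those tested, where chance gives 10%. DESeq2 called 58 genes (55 higher, 3 lower), limma-voom 0 with 299 at an unadjusted p under 0.05, and limma on the deposited FPKM 0 in each of 3 settings, with 188 to 733 at an unadjusted p under 0.05. On simulated counts DESeq2 had called 77 unchanged genes and edgeR 6, so a call by DESeq2 alone is weak evidence. Of the 55 higher in DESeq2, 42 were more than 4-fold lower in Lyz2-Cre 2 than in Lyz2-Cre 1 and 3. On the stomach and intestinal list were 11 of the 55. That list does not hold every gene of this pattern: Mgam, not on it, was at 18.3, 1.30 and 17.1 CPM in Lyz2-Cre 1, 2 and 3. In Lyz2-Cre 2, 45 of the 55 were above every floxed library. Their levels there ranged from 0.05 CPM (Adh6a), about what a count of 0 allows, to 5.76 CPM (Spp1). Fabp6 and Sis were at 0.07 CPM. Lyz2-Cre 2 was part of the test that picked the 55 genes, which favours genes raised there. The count of 45 is thus no separate evidence that Lyz2-Cre 2 shares the rise. Leaving out Lyz2-Cre 2 gave 24 calls by edgeR (11 higher, 13 lower), and the number at an unadjusted p under 0.05 was 818 without Lyz2-Cre 2, 385 without Lyz2-Cre 1 and 148 without Lyz2-Cre 3.

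The series title asks about M2 polarisation, the alternative activation of macrophages, and the M2 markers were not called as a group. The 16 abundant macrophage genes took only 0.0283% to 0.0680% of the counts. The M2, M1 and PI3K/AKT levels given here and below are therefore those of whole libraries and cannot decide what macrophages did. Of 19 tested M2 markers, 8 were higher and 11 lower in the libraries labelled Lyz2-Cre, with 0 called over all genes and 0 adjusted over the list alone, by edgeR (0 also at an unadjusted p under 0.05). Their median log2 fold change was -0.05, the mean was 0.16 and camera's direction was down at an adjusted p of 0.742, so the mean differed in sign from the median and the test. Tgm2, a transglutaminase, was at 1899, 1068 and 299 CPM in the floxed libraries and at 363, 2085 and 1070 CPM in those labelled Lyz2-Cre. Il4ra, the receptor of interleukin 4, averaged 78.5 ± 48.0 and 77.7 ± 47.9 CPM, the scavenger receptor Stab1 57.5 ± 20.7 and 55.1 ± 20.9 CPM, and the transcription factor Klf4 33.5 ± 3.03 and 32.3 ± 0.646 CPM (SD, n = 3 each). The direction turned to up without Lyz2-Cre 1, at an adjusted p of 0.191 by camera.

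Markers of M1, the classical activation state, were spread widely within both labels. Of 20 tested M1 markers, 15 were higher and 5 lower in the libraries labelled Lyz2-Cre, 0 were called by edgeR over all genes or adjusted over the list alone, and 1, the nitric oxide synthase Nos2 with a log2 fold change of 0.77, had an unadjusted p under 0.05. The median log2 fold change of the list was 0.47 at an adjusted p of 0.156 by camera, and 0.943 with an estimated correlation. Saa3, an acute phase protein, was at 541, 546 and 92.8 CPM in the floxed libraries and at 64.4, 563 and 410 CPM in those labelled Lyz2-Cre. Socs3, a feedback inhibitor of cytokine signalling, averaged 37.6 ± 30.1 and 55.5 ± 43.5 CPM and was lowest in floxed 3, at 4.45 CPM, and Lyz2-Cre 1, at 7.13 CPM. Cd38, an ectoenzyme, averaged 28.9 ± 5.07 and 29.95 ± 9.68 CPM and the arginine transporter Slc7a2 20.8 ± 11.2 and 23.7 ± 20.3 CPM (SD, n = 3 each). Camera called the M1 list higher without Lyz2-Cre 1, at an adjusted p of 0.000513, and without floxed 2, at 0.00466, and its direction was down without floxed 3, at 0.826, or without Lyz2-Cre 2, at 0.891.

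Other inflammatory groups followed the same libraries. The NF-kappaB targets, chemokines, type I interferon genes, interferon-gamma inducible GTPases, M1 markers and matrix remodelling genes, 6 lists in all, each had their lowest levels in floxed 3 and Lyz2-Cre 1. For the NF-kappaB targets these levels were -1.05 and -1.12 log2 CPM relative to the mean of the libraries. The cardiomyocyte genes had their highest medians in floxed 3 and Lyz2-Cre 1, at 2933 and 3658 CPM, against 1050 to 1528 CPM in the other libraries. The median log2 fold changes of the inflammatory lists were 0.17 (14 higher, 4 lower), 0.32 (14 and 4), 0.16 (15 and 6) and -0.12 (6 and 7) for NF-kappaB targets, chemokines, type I interferon and interferon-gamma genes. The adjusted p were 0.641, 0.815, 0.693 and 0.742 by camera, and 0 members were called by edgeR in these 4 lists, over all genes or adjusted over the list alone. Without Lyz2-Cre 1, camera called the NF-kappaB, chemokine and type I interferon lists higher, at 0.000513, 0.0443 and 0.00655, and without floxed 3 it called the interferon-gamma list lower, at 0.00111. These calls used the preset correlation. With all libraries, the estimated correlation was 0.79, 0.45, 0.7 and 0.98 in these 4 lists, and camera with it gave each an adjusted p of 0.981.

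**Figure D4:**
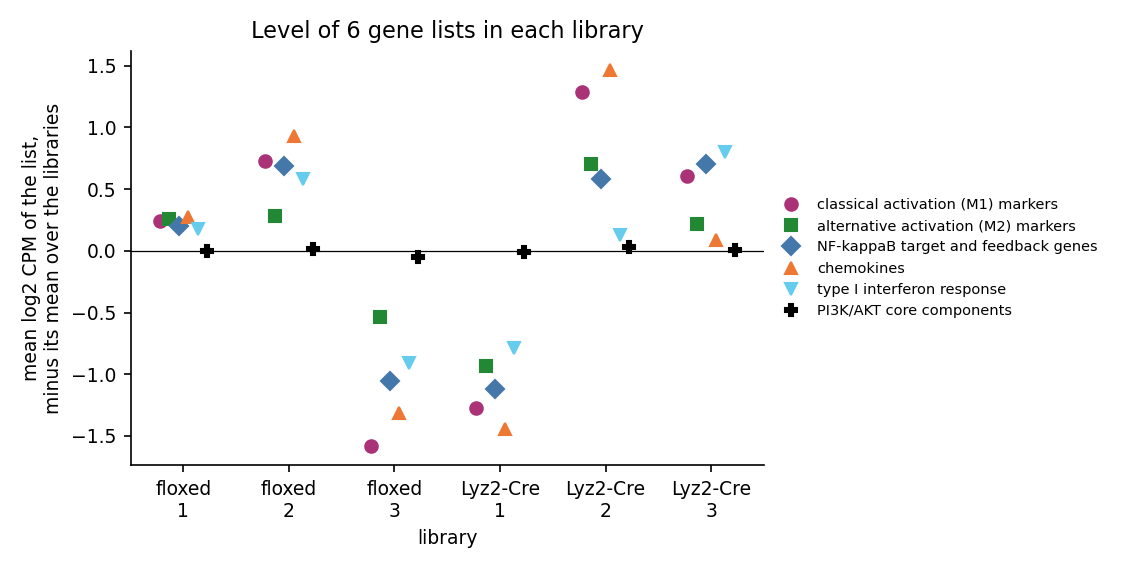
Level of 6 gene lists in each library, as the mean log2 CPM of the list minus its mean over the libraries. Floxed 3 and Lyz2-Cre 1 are lowest for the M1, NF-kappaB, chemokine, type I interferon and M2 lists, and the PI3K/AKT core list stays within -0.047 to 0.033.

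For PI3K/AKT signalling, the pathway that the series title names, the core kinases and regulators had nearly equal levels under both labels. Of 28 tested core components, 15 were higher and 13 lower, with log2 fold changes from -0.26 to 0.32, a median of 0.03 and 0 called by edgeR over all genes or adjusted over the list alone (0 at an unadjusted p under 0.05). Camera gave the core list an adjusted p of 0.742. Akt1, a serine/threonine kinase of the pathway, averaged 176 ± 11.6 and 182 ± 8.02 CPM (SD, n = 3 each), with a 95% interval of its log2 fold change from -0.40 to 0.51. Akt2 averaged 133 ± 26.2 and 137 ± 29.6 CPM and the regulatory subunit Pik3r1 189 ± 43.5 and 197 ± 33.8 CPM (SD, n = 3 each). These are levels of RNA and not of phosphorylated protein. Of 44 upstream ligands, receptors and matrix genes, a list that holds Spp1, 35 were higher and 9 lower with a median of 0.16, an adjusted p of 0.0734 by camera and 0.492 with an estimated correlation. It was called higher without floxed 1, at an adjusted p of 0.0406, or without Lyz2-Cre 1, at 0.0201, by camera.

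Genes of the cell cycle, markers of B and plasma cells and genes of MHC class II antigen presentation were the groups that camera called, all higher in the libraries labelled Lyz2-Cre. The calls were lost with an estimated correlation, at adjusted p of 0.492, 0.256 and 0.645, and with fry, at 0.777, 0.311 and 0.870. Of 21 cell cycle genes 20 were higher, with a median log2 fold change of 0.51 and an adjusted p of 7.07e-11. Mki67, a marker of dividing cells, averaged 2.15 ± 0.912 and 5.70 ± 1.43 CPM, and the DNA topoisomerase Top2a 1.17 ± 0.714 and 3.43 ± 1.33 CPM (SD, n = 3 each). Of 11 B and plasma cell markers 10 were higher and Ebf1 was lower, with a median of 0.91 and an adjusted p of 8.47e-07. Jchain, the joining chain of secreted IgA and IgM, was at 0.54, 1.03 and 0.64 CPM in the floxed libraries and at 8.80, 1.61 and 4.32 CPM in those labelled Lyz2-Cre, and Igkc, the kappa light chain, at 2.34 to 4.50 CPM and at 22.04, 4.72 and 7.89 CPM. All 9 MHC class II genes were higher, with a median of 0.35 and an adjusted p of 0.0346, while Cd74, the invariant chain, averaged 45.6 ± 11.9 CPM in the libraries labelled Lyz2-Cre and was at 33.4 to 56.2 CPM in the floxed ones. No member of the 3 lists was called by edgeR over all genes or adjusted over the list alone, and 5, 2 and 0 members had an unadjusted p under 0.05.

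The levels of the cell cycle and B cell lists were highest in Lyz2-Cre 1 and 3, the libraries with the most stomach and intestinal transcripts, and lay above every floxed library in Lyz2-Cre 2 as well. Relative to the mean of the libraries, the cell cycle list was at -0.21, -0.11 and -1.11 log2 CPM in the floxed libraries and at 0.67, -0.06 and 0.82 in Lyz2-Cre 1, 2 and 3. The B cell list was at -0.51, -0.42 and -0.50 in the floxed libraries and at 0.93, 0.09 and 0.41 in Lyz2-Cre 1, 2 and 3. The MHC class II list was at -0.65, 0.07 and -0.19 in the floxed libraries and at 0.55, -0.08 and 0.31 in these 3, so that Lyz2-Cre 2 lay below floxed 2. With a term for the libraries that hold the stomach and intestinal transcripts, which leaves Lyz2-Cre 2 alone to set against the floxed libraries, the adjusted p was 0.113, 0.0561 and 0.526 by camera for the cell cycle, B cell and MHC class II lists. With 1 library on that side this does not show that the calls depend on these transcripts, and the libraries that hold them are all labelled Lyz2-Cre, so no difference could be had within them. Over all 32 lists tested, 3 were called, and 14 without Lyz2-Cre 1, 7 without floxed 2 and 5 without floxed 3. The MHC class II list was not called without floxed 1, at 0.672, without Lyz2-Cre 1, at 0.108, without Lyz2-Cre 2, at 0.139, or without Lyz2-Cre 3, at 0.0933.

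**Figure D5:**
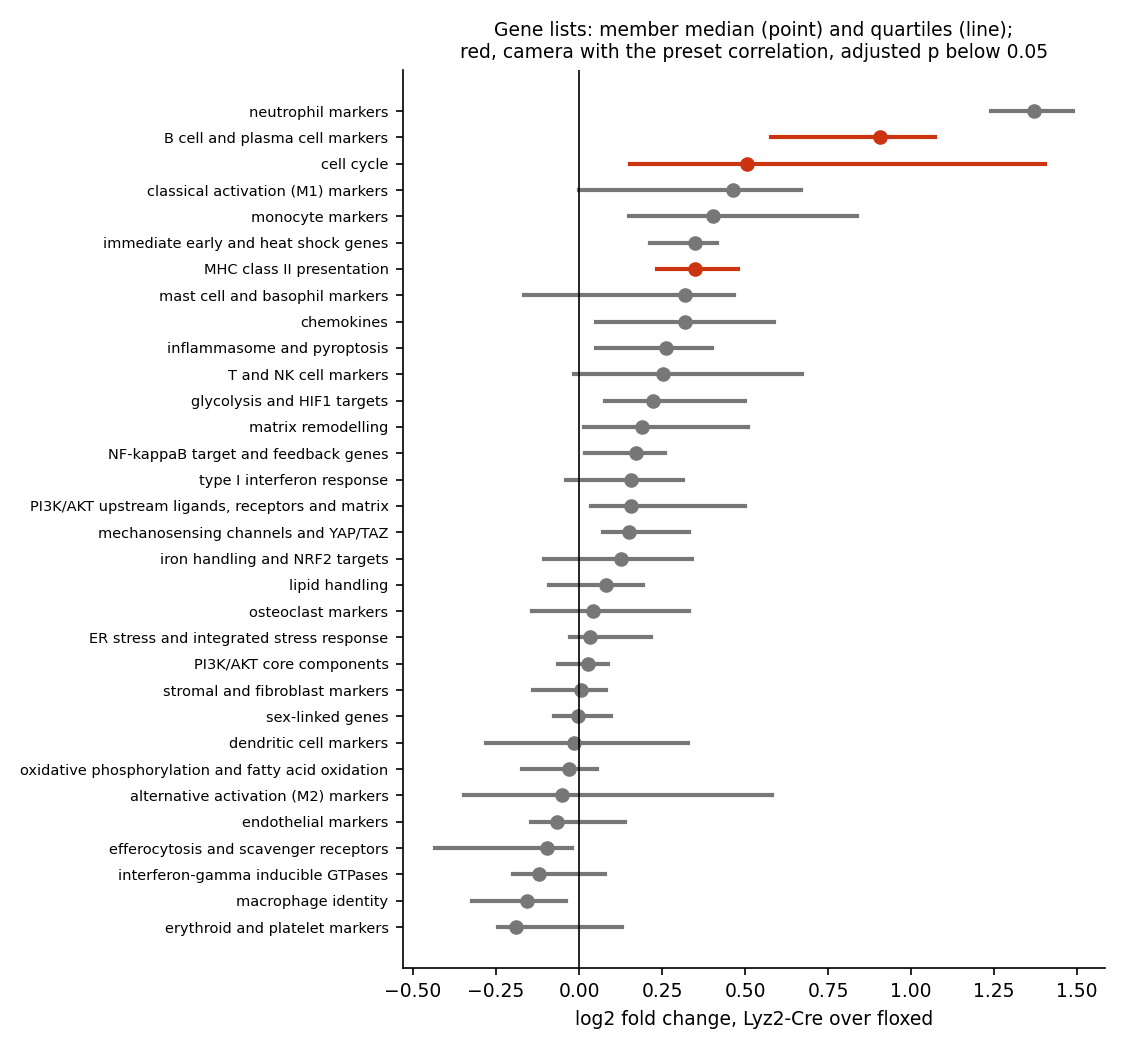
Median (point) and quartiles (line) of the log2 fold change of the members of each of the 32 tested gene lists, libraries labelled Lyz2-Cre over floxed, with lists called by camera at the preset correlation in red. The cell cycle, B cell and MHC class II lists are in red at medians of 0.51, 0.91 and 0.35, and the PI3K/AKT core list lies at 0.03.

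The remaining lists were not called with all libraries, TMM factors, the default filter and no replicate block, and 0 of their members were called by edgeR over all genes or adjusted over the list alone. All 16 immediate early and heat shock genes, such as Fos and Jun, were higher with a median of 0.35 and an adjusted p of 0.0521 by camera, and of the 13 inflammasome genes 10 were higher with a median of 0.26 and an adjusted p of 0.0521. Of 21 mechanosensing genes, which include stretch-activated channels and YAP/TAZ targets, 19 were higher with a median of 0.15 and an adjusted p of 0.0868. Of 22 glycolysis and HIF1 targets 17 were higher with a median of 0.22 and an adjusted p of 0.0983, Bnip3 being among the 5 lower. With the strict filter camera called these 4 lists, at adjusted p of 0.0153, 0.0259, 0.0259 and 0.0343, and with an estimated correlation none, at 0.943, 0.492, 0.657 and 0.645. With a replicate block the immediate early and inflammasome lists were called, both at 0.0471 by camera. The immediate early list was also called with upper-quartile factors, at 0.0469, without floxed 1, at 0.0170, without floxed 2, at 0.0109, and without Lyz2-Cre 1, at 0.000513, by camera. Mechanosensing and glycolysis were called without Lyz2-Cre 1 as well, at 0.0149 and 0.0444. The median was -0.03 for oxidative phosphorylation (adjusted p 0.231), -0.10 for efferocytosis (0.263), 0.08 for lipid handling (0.867) and 0.03 for endoplasmic reticulum stress (0.641). Iron handling and matrix remodelling had positive medians, 0.13 and 0.19, while camera's direction was down, at 0.742 and 0.985.

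Among the cell type lists, macrophage identity genes were lower in 12 of 15 cases with a median of -0.16 and an adjusted p of 0.288 by camera. All 10 neutrophil markers had positive log2 fold changes with a median of 1.37 while camera's direction was down at 0.985, and S100a9, a neutrophil calcium-binding protein, was at 193 CPM in Lyz2-Cre 2 and 2.63 and 12.3 CPM in Lyz2-Cre 1 and 3. Monocyte markers had a median of 0.40 (0.288), T and NK cell markers 0.25 (0.198), mast cell markers 0.32 (0.742), osteoclast markers 0.04 (0.985), erythroid and platelet markers -0.19 (0.841) and endothelial markers -0.07 (0.742), adjusted p by camera in parentheses. Dendritic cell markers had a median of -0.02 and a mean of 0.17, direction up at 0.736, and stromal markers a median of 0.01 and a mean of -0.03, direction down at 0.641. The sex-linked genes had a median of -0.003 and a mean of 0.59, direction up at 0.636, with the Y-linked Ddx3y at 81.2 to 98.3 CPM in all 6 libraries. Xist, which is expressed from the inactive X chromosome, was at 0, 0.40 and 0 CPM in the floxed libraries and at 2.16, 0.41 and 1.07 CPM in those labelled Lyz2-Cre, a log2 fold change of 3.15 at an adjusted p of 0.9999 by edgeR. Only 2 eosinophil markers were measured, too few for a test, with a median of 0.35. The calls of these lists also depended on single libraries, neutrophil markers being called higher without Lyz2-Cre 1, at an adjusted p of 0.0409, and lower without Lyz2-Cre 2, at 0.00966, by camera. Both calls used the preset correlation. With all libraries, the estimated correlation of the neutrophil list was 0.93, and camera with it gave an adjusted p of 0.994.

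No transcript passed the test, which had no power on simulated transcripts. Of 39906 transcripts, edgeR called 0, with 748 at an unadjusted p under 0.05 where chance gives 1995.3 and a smallest adjusted p of 0.2748. DESeq2 called 247 transcripts, 159 of them higher. The Spp1 transcript ENSMUST00000112748 had 0 counts in each floxed library and 59, 128 and 240 in those labelled Lyz2-Cre, and ENSMUST00000031243 had 126, 0 and 0 against 490, 214 and 344. Of the Piezo1 transcripts, ENSMUST00000156333 had 2641, 2347 and 1333 counts in the floxed libraries and 1532, 2017 and 2862 in those labelled Lyz2-Cre, and ENSMUST00000067252 had 186, 178 and 500 against 1148, 1005 and 159. The transcript counts are estimates, which divide reads between transcripts of a gene.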

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

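The term for stomach and intestinal transcripts, the comparisons of Lyz2-Cre 2 with the floxed libraries and of 2 libraries with 2, the KEGG pathways and the fits without mitochondrial genes or robust dispersion were chosen after the data were seen. Of 240 alternative values for the results that answer a comparison, 182 stayed the same, 17 were weaker, 11 stronger, 24 moved and 6 reversed. Staying the same meant the same direction and side of the threshold for a test, and a similar number for a count. Of 550 values for 31 named genes 512 stayed within 1 SD and 38 moved. A reversal was counted only for a named gene called in the main fit. As 0 were called there, no reversal of a named gene could be counted. DESeq2 called 58 genes against 0, gave 620 at an unadjusted p under 0.05 against 242, gave Spp1 a called log2 fold change of 2.34 and called 247 transcripts against 0. On simulated counts of genes it had called 77 unchanged genes, against 6 by edgeR. The number at an unadjusted p under 0.05 was 584 with no filter and 126 with the strict filter, which test other numbers of genes, 733 for unfiltered FPKM, 418 with the term, 435 for Lyz2-Cre 2, and 148 to 818 with each library left out in turn, while calls ranged from 0 to 24. Lists called, 3 at first, were 8 with the strict filter, 10 with the term, 9 for Lyz2-Cre 2, 9 for 2 libraries with 2, 0 with an estimated correlation, 0 by fry, 24 of 304 KEGG pathways, and 3 to 14 with each library left out. The M2 list reversed to up with the term (adjusted p 0.182), for Lyz2-Cre 2 (0.0905), for 2 libraries with 2 (0.175) and without Lyz2-Cre 1, its range being 0.191 to 0.858 with each library left out. The M1 list was called with the term (0.000437), for Lyz2-Cre 2 (7.11e-05) and for 2 libraries with 2 (0.0188), with a range of 0.000513 to 0.891 that includes reversals without floxed 3 and without Lyz2-Cre 2. The upstream PI3K/AKT list was called with the strict filter (0.0153), the term (0.0373) and 2 libraries with 2 (0.00573), with a range of 0.0201 to 0.799. The cell cycle list lost its call with an estimated correlation (0.492), fry (0.777), the term (0.113) and Lyz2-Cre 2 (0.163), the B cell list likewise (0.256, 0.311, 0.0561 and 0.0841), and the MHC class II list likewise (0.645, 0.870, 0.526 and 0.516), with no filter (0.121) and in a range of 0.00466 to 0.672. The term leaves Lyz2-Cre 2 alone on its side, as the comparison of Lyz2-Cre 2 with the floxed libraries does, so both rest on 1 library assumed to vary like the floxed ones. Gains and losses of calls there do not show a dependence on the stomach and intestinal transcripts. The cause of the changes was not tested. With the replicate number as a replicate block, 0 genes were called, 104 were at an unadjusted p under 0.05 and 5 lists were called, the inflammasome and immediate early lists being added, and no other call changed. Same-numbered libraries correlated at -0.469, 0.171 and -0.373 in their deviations, and the highest value, 0.594, joined floxed 3 and Lyz2-Cre 1. The check thus gave no sign of a pairing by number. With 3 libraries per label it cannot exclude a pairing hidden by larger differences between libraries. Depth, 56844600 to 61420576 counts, limits the genes near the floor of 0.0457 to 0.0599 CPM.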

Other observations

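The tests of heart muscle, stomach and intestinal and low inflammatory transcripts described here were chosen after the results were seen, and the counts of other splits of the libraries were planned before. Nppb, the ventricular natriuretic peptide that heart muscle cells make under load, was at 87.3, 57.5 and 56.96 CPM in the floxed libraries and at 141, 307 and 142 CPM in those labelled Lyz2-Cre. The means were 67.3 ± 17.3 and 197 ± 95.3 CPM (SD, n = 3 each), with a log2 fold change of 1.55 (SE 0.38) and an adjusted p of 0.9999 by edgeR's quasi-likelihood test, while Nppa, the atrial peptide, averaged 132 ± 32.6 and 151 ± 73.9 CPM. Lyz2-Cre 2 had the most of the neutrophil transcripts S100a8 and S100a9, at 97.2 and 193 CPM, followed by floxed 1, at 26.6 and 52.8 CPM. Adgre1, the F4/80 antigen of macrophages, was highest in floxed 3, at 66.8 CPM, against 6.39 to 32.5 CPM in the other 5 libraries. These genes were chosen after their values were seen.

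In the KEGG pathways, camera with the preset correlation called 24 of 304, 6 higher and 18 lower in the libraries labelled Lyz2-Cre, and 0 with an estimated correlation. Steroid hormone biosynthesis was lower with a median log2 fold change of -0.73 and an adjusted p of 3.98e-08, which was 0.829 with an estimated correlation. Complement and coagulation cascades had a median of -0.33 and an adjusted p of 2.57e-06, and oxidative phosphorylation -0.16 and 2.57e-06. Fat digestion and absorption was higher with a median of 0.23 and an adjusted p of 0.000232, and the intestinal network for IgA production with 0.30 and 0.00244. All were at an adjusted p of 0.829 with an estimated correlation. Beside them, the liver genes summed to 99.3, 1992 and 923 CPM in Lyz2-Cre 1, 2 and 3 against 1260 to 1637 CPM in the floxed libraries, and the stomach and intestinal genes to 830, 22.1 and 811 CPM against 18.2 to 26.0 CPM. At the transcript level, 22 transcripts had 0 counts in every floxed library and at least 50 in each library labelled Lyz2-Cre, and 13 the opposite. A transcript of Ap2a1, an adaptor protein of endocytosis, had 2828, 2799 and 2568 counts in the libraries labelled Lyz2-Cre, and one of Slmap, a membrane protein of heart and other muscle, had 2509, 1627 and 2192 in the floxed libraries. The median absolute log2 fold change of the genes of these transcripts was 0.19, and 1 of them, Spp1, had an unadjusted p under 0.05.

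Heart muscle transcripts took 4.18% to 7.90% of the counts in libraries labelled as macrophages, with Myh6 at up to 15591 CPM and Tnnt2 at up to 5554 CPM. Trace carry-over of heart RNA into macrophage libraries is argued against, since the summed CPM of the abundant macrophage genes reached at most 0.0155 of that of the cardiomyocyte genes. The values are consistent with RNA of whole heart tissue in place of macrophage RNA, since the median of the endothelial markers was at least 2.97 times that of the macrophage identity genes in every library. This remains a hypothesis, formed and tested on the same libraries, and the labels name no heart sample. Whether the Piezo1 counts came from cells that do not express Lyz2-Cre was not tested.

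Stomach and intestinal transcripts were high in Lyz2-Cre 1 and 3, with Fabp2 at 143 and 124 CPM and Pgc at 119 and 159 CPM. In Lyz2-Cre 2 the listed genes summed to 0.85 times the highest floxed library, floxed 3. Anpep and Cldn15 made up much of both sums, at 13.1 and 6.45 CPM in floxed 3 and 6.03 and 7.47 CPM in Lyz2-Cre 2. The ratio therefore does not show that the other listed genes stayed at floxed levels. Apoa4 at 3.89 CPM and Epcam at 0.26 CPM were above every floxed library there. The sums of 830, 22.1 and 811 CPM within the label Lyz2-Cre argue against the genotype as the whole cause. A foreign RNA of the same makeup in Lyz2-Cre 1 and 3 may be the source. Over the 24 genes with at least 5 CPM in both, the log2 ratio between these libraries had an SD of 0.296. Over all 35 genes the SD was 0.645, with Tff2 at 9.22 and 3.03 CPM and Reg1 at 0.23 and 1.58 CPM, so a shared makeup stays open. The liver genes differed by an SD of 0.109 to 0.270 between floxed 1 to 3 and Lyz2-Cre 2, over 29 genes, and by 1.58 between floxed 1 and Lyz2-Cre 3, over 22 genes. In Lyz2-Cre 3, Fga and Fgb, fibrinogen chains, were at 213 and 164 CPM beside Alb at 213 CPM. How such RNA entered the libraries was not tested.

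Low inflammatory transcripts in floxed 3 and Lyz2-Cre 1 are found in 1 library of each label. The Lyz2-Cre genotype as the whole cause is argued against, since each lay apart from libraries of its own label. In all 6 lists its gap to the nearest of these was at least 1.11 times the distance between the other 2. Both libraries had been picked as the lowest in these same lists, so the 6 ratios are not independent support. For the NF-kappaB list floxed 3 was at -1.05 log2 CPM against 0.21 and 0.69 in floxed 1 and 2, and Lyz2-Cre 1 at -1.12 against 0.58 and 0.70 in Lyz2-Cre 2 and 3. Stomach and intestinal transcripts are argued against as the cause, since these genes were 31.9 times higher in Lyz2-Cre 1 than in floxed 3, and liver transcripts likewise, since those genes were 16.5 times higher in floxed 3 than in Lyz2-Cre 1. A different LPS exposure or time could be the cause, but the labels give 1 dose for all libraries, so it cannot be told apart from other causes here. The 18 cardiomyocyte genes were highest in the same libraries. They summed to 67960 CPM in floxed 3 and 78520 CPM in Lyz2-Cre 1, against 40600 to 53290 CPM in the other 4. Whether the tissue makeup of the libraries is the cause was not tested. The first principal component of log2 CPM, 49.5% of the variance, placed floxed 3 and Lyz2-Cre 1 apart from the other 4, at 68.7 and 118. The second, 24.4% of the variance, placed them on opposite sides, at 81.8 and -43.9, with Lyz2-Cre 3 at -72.8.

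The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 0 genes and the highest other split 0, so all 10 gave at least as many. At an unadjusted p under 0.05 the real split gave 242 genes and the highest other split 3903, with 7 splits at least as high, and for lists called the values were 3 and 11, again with 7 splits. For transcripts called they were 0 and 1, with 10 splits, and for transcripts at 0 under a single label 35 and 58, with 6 splits. The split with 3903 genes set floxed 1 with Lyz2-Cre 2 and 3 against floxed 2, floxed 3 and Lyz2-Cre 1, and gave many times the real number, which points to a structure of the libraries other than the label.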
